A study of Homo sapiens with 12 samples.

How the data were processed

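Total RNA from 12 cultures of 4 lines was amplified with a T7 oligo-dT primer, labelled with biotin and hybridised to 3′ expression arrays with 54675 probe sets, per the labels' protocols. Each line had 3 biological replicates. The deposited values are log2 values made with robust multi-array averaging (RMA), a tool named with limma in the submitters' processing notes; versions, parameters and the role of limma are not given in the sources used here. The values bear out a log2 scale, with array medians of 5.74 to 5.77 and values from 3.00 to 15.28. The number of arrays limits the precision, and low values carry no detection call. RMA normalises quantiles and summarises probes over all arrays, so a level is relative to the other arrays and small true differences near the background are compressed. The scanner files were not used here.

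Probe sets were named through the platform annotation of 2016, with symbols updated by gene ID through a RefSeq table of assembly GRCh38.p14, of which only names and gene order were used. The annotation listed 42898 probe sets, of which 41097 had 1 gene and 1801 several, and 11777 were unnamed here. Gene IDs matched for 41043 of the single-gene probe sets and 54 kept the older symbol. Each of the 19775 genes was represented by the single-gene probe set with the highest mean over all 12 arrays. Genes found only on probe sets of several genes were not tested, and of 647 entries in the gene lists 584 were measured.

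The differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 model with a mean for each of the 4 lines and all 12 arrays, without a filter on low values. P-values were adjusted by Benjamini and Hochberg over all genes, and an adjusted p under 0.05 was a call. The comparisons were SKR6CA with SKR6-Vector, SKR6LR with SKR6, SKR6-Vector with SKR6, and the difference between the first 2 effects. The labels call the replicates biological, and whether they were separate derivations of a line is not given. P-values and SEs therefore rest on the spread among cultures. For each gene this spread was pooled over the 4 lines, so it is not that of the 2 lines compared. The SKR6LR replicates varied most. On average this widens the SEs of comparisons without SKR6LR and narrows those of SKR6LR against SKR6.

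The 30 gene lists were fixed before the data were examined and were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison. Camera was repeated with a correlation estimated for each list. Fry tests whether a list's genes moved on balance in 1 direction and does not compare them with other genes. Counts "adjusted over the list alone" apply the adjustment within the list. The design, the other alternatives and the rule for named genes were likewise fixed before the data were examined. The rule took RELA, ERBB2, EGFR and ERBB3; the 10 largest rises and 10 largest falls per main comparison (5 and 5 for the vector) among called genes without overlap between arrays; up to 4 called members with the largest differences from each called list and from the NF-kB target, anti-apoptotic, pro-apoptotic and ERBB lists; the 5 genes moving most in both comparisons in each direction pattern; and the 5 largest differences between effects each way. Members of lists named outside this rule were chosen after their values were seen: CCL2, SOD2, ICAM1, CXCL1, IER3, LCN2 with active p65, MCL1 and XIAP in SKR6LR, KRT15, HLA-DMA, CDKN1B and EBP in SKR6LR, the members so marked in the text, and all list members named in the other observations.

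The alternatives were the replicate number as a block, leaving out each array, cyclic loess, median centring, a mean-variance trend with robust fitting, array weights, only the compared arrays, a filter on low values, the mean of probe sets, no _x_at or _s_at probe sets, every probe set, an adjusted p under 0.01, the other control line, an estimated correlation and fry. One weight per group was added after the data were seen, because the SKR6LR arrays varied more among themselves.

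The model was tested on simulated data of 19775 genes with 200 changed genes. With 1 spread for all lines, 71.6% of changes of 0.5, 98.5% of changes of 1 and 100% of changes of 2 on the log2 scale were recovered for SKR6LR against SKR6, and 5.76% of the calls were false. For SKR6CA against SKR6-Vector these shares were 71.6%, 95.5% and 100%, with 2.20% false, and for SKR6-Vector against SKR6 64.2%, 100% and 100%, with 2.76% false. When each line kept its own spread, 28.2% of the calls for SKR6LR against SKR6 were false (73 of 19575 unchanged genes), which exceeded a limit of 10% first set for this test. The limit was then applied only to data simulated with 1 spread, and the design was kept as fixed. Group weights brought the false share for SKR6LR against SKR6 to 2.79%, while recovery of changes of 1 went from 100% to 91.0%. In the other comparisons group weights raised the false share. It went from 0.559% to 6.73% for SKR6CA against SKR6-Vector and from 0.571% to 7.35% for SKR6-Vector against SKR6. Null lists passed an unadjusted p of 0.05 in at most 3 of 100 draws. The simulated errors were independent between genes, so this does not test camera on lists whose genes are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.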

Results

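Gene expression was measured in 4 lines that descend from SKBR-3, a human breast cancer line whose HER2 gene (ERBB2) is amplified. SKR6 was obtained by sorting SKBR-3 for cells with high HER2. SKR6-Vector carried an empty retroviral vector and SKR6CA carried a retrovirus for a constitutively active form of the NF-kB subunit p65 (RELA); both were selected with puromycin. SKR6LR was kept for months in lapatinib, an inhibitor of the EGFR and HER2 kinases, at doses that rose from 0.2 to 5 µM. Each line had 3 biological replicates with 1 array each, 12 arrays in all, and RNA was taken after 48 hours of culture. The series title names NF-kB activation, protection from apoptosis and drug resistance as its subject. The array medians lay between 5.74 and 5.77 on the log2 scale. Values over the whole array ran from 3.00 to 15.28.

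The SKR6LR arrays stood apart from the other lines. Their correlation with arrays of the other lines was 0.914 to 0.933 across the 19775 genes, against 0.988 to 0.990 among the 3 other lines. The first principal component held 79.4% of the variance and separated SKR6LR, and the second held 8.65% and separated SKR6-Vector from SKR6 and SKR6CA. The SKR6LR replicates also varied more among themselves, with a replicate SD of 0.209 on the log2 scale against 0.0958 for SKR6, 0.0965 for SKR6-Vector and 0.107 for SKR6CA. The 3′ minus 5′ difference of the actin control probe sets, a sign of RNA quality, was 2.32 in SKR6LR replicate 3 and lay between 1.03 and 1.73 on the 11 other arrays. The GAPDH control gave 0.159, 0.229 and 0.513 for SKR6LR replicates 1, 2 and 3, and at most 0.193 on the 9 arrays of the other lines.

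**Figure D1:**
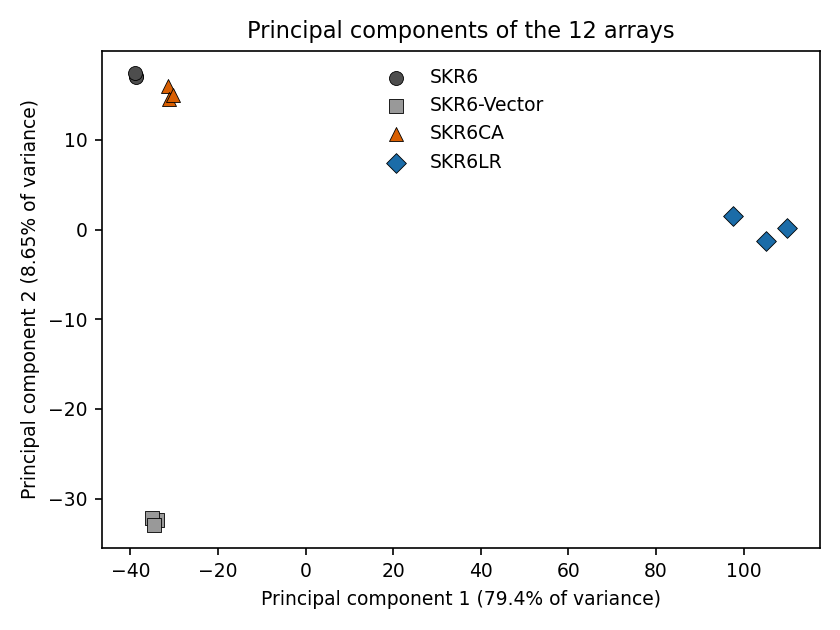
Principal components of the 12 arrays; each point is 1 array, and the axes give component scores with the percent of variance each component holds. The SKR6LR arrays lie apart on component 1, which holds 79.4% of the variance, and the SKR6-Vector arrays on component 2, which holds 8.65%.

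The comparison of SKR6CA with SKR6-Vector asked what active p65 changed beyond the vector and the selection. Classical NF-kB targets were higher with active p65. TNFAIP3, an inducible inhibitor of NF-kB signalling, rose from 7.85 ± 0.07 to 10.69 ± 0.07 (mean ± SD, n = 3 and 3), a log2 difference of 2.84 (SE 0.299, adjusted p = 1.91e-05). Its SE uses the spread pooled over the 4 lines, and its SKR6LR values ran from 10.72 to 12.45. The chemokine CCL20 rose by 4.02 (SE 0.222, adjusted p = 7.91e-08) and the cytokine TNF by 2.60 (SE 0.240, adjusted p = 6.24e-06). The BCL2 family member BCL2A1 rose by 1.93 (SE 0.319, adjusted p = 0.000615). In all 4 genes every SKR6CA array lay above every SKR6-Vector array.

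Of 42 measured NF-kB target genes, 19 rose, 2 fell and 21 did not pass the test, with a median log2 difference of 0.40 (camera adjusted p = 8.63e-06; adjusted p = 0.700 with an estimated correlation). When adjusted over the list alone, 21 rose and 4 fell. CCL2 rose by 2.07, the superoxide dismutase SOD2 by 1.60, the adhesion molecule ICAM1 by 1.32 and CXCL1 by 1.21. The 2 members that fell were LCN2, by 1.37, and IER3, by 0.23, named after their values were seen. LCN2 had itself risen in SKR6-Vector over SKR6, as given below, so its fall is measured against a raised level. The complement factor CFB had a log2 difference of 4.85 on an _s_at probe set, a kind that can match several transcripts, but 0.065 on its other probe set. Among NF-kB subunits and upstream regulators 9 of 22 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0202; adjusted p = 0.700 with an estimated correlation, 0.0537 with fry). IKBKE, an IKK-related kinase, rose by 1.05, the inhibitor NFKBIA by 0.87 and the subunit RELB by 0.73. The RELA transcript itself showed differences of -0.056 (adjusted p = 0.753) and, on the second probe set, 0.20 (adjusted p = 0.259). Whether these probe sets report the transgene is not known, since probe and construct sequences were not analysed here.

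**Figure D2:**
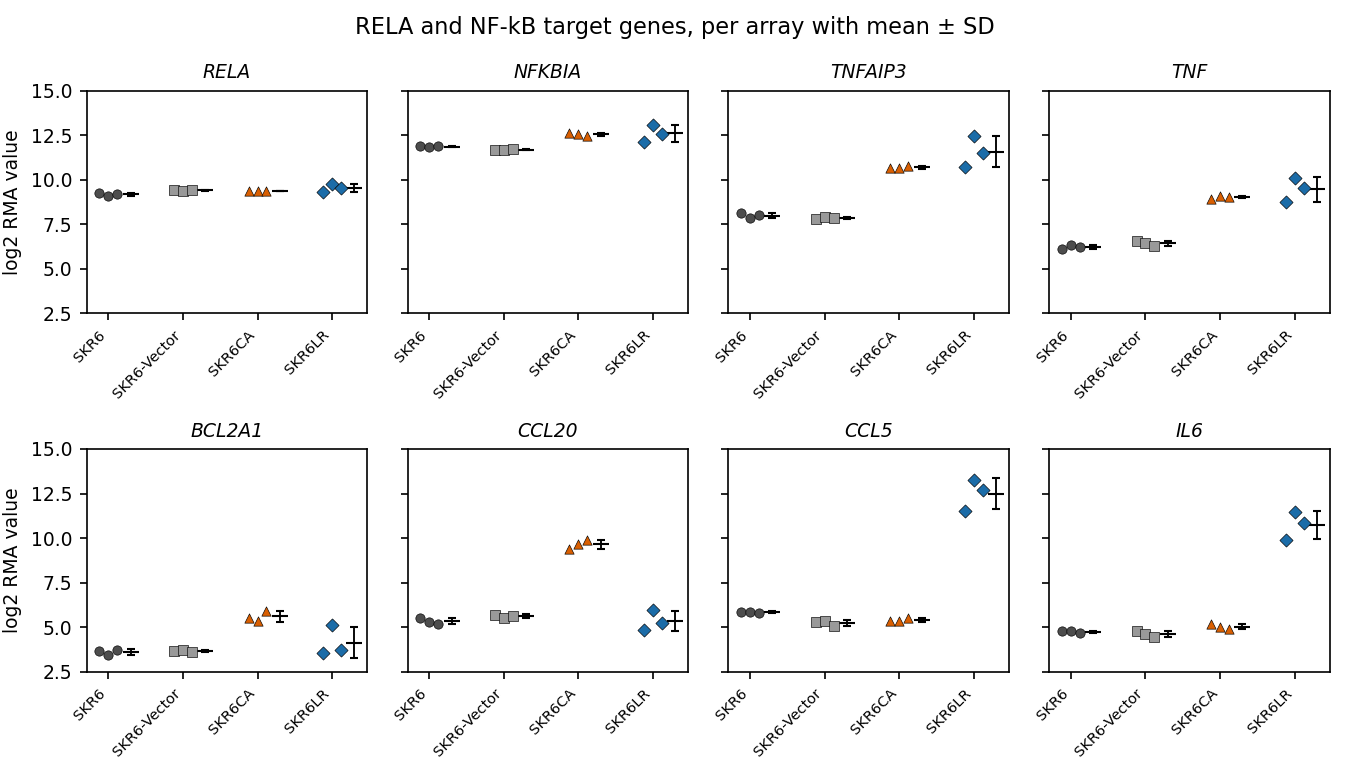
RELA and 7 NF-kB target genes on the 12 arrays; points are single arrays in log2 RMA values, and the bars beside them give the mean ± SD of the 3 replicates. TNFAIP3, TNF and NFKBIA are higher in SKR6CA and SKR6LR than in SKR6 and SKR6-Vector, CCL20 and BCL2A1 passed the test in SKR6CA and not in SKR6LR, and CCL5 and IL6 passed it in SKR6LR and not in SKR6CA.

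Genes of cell death moved in both directions. Of 15 anti-apoptotic genes 4 rose, 1 fell and 10 did not pass the test, and the list was not called (camera adjusted p = 0.680, median 0.0093). Counts adjusted over the list alone were 4 and 4. The 4 that rose were TNFAIP3, BCL2A1, GADD45B (by 1.12) and CFLAR (by 0.57). The CFLAR difference became -0.000479 when all its probe sets were averaged. CFLAR also lost the call without any 1 of the 6 compared arrays, although its difference stayed at 0.55 to 0.59 (adjusted p = 0.0577 to 0.0757). IER3 was the one that fell. Of 22 pro-apoptotic genes 4 rose and 7 fell (camera adjusted p = 0.769), with PMAIP1 higher by 1.77 and BMF lower, a difference of -1.08, although BMF was higher than in SKR6 by 0.21 (adjusted p = 0.0468). ERBB2 differed by 0.12 (adjusted p = 0.156; called under 4 alternatives with the same control, at 0.0250 to 0.0461, and higher than in SKR6 by 0.21, at 0.0162), and EGFR rose by 0.46 (adjusted p = 0.000172). ERBB3 fell by 0.37 (adjusted p = 0.00212), but was not called with the mean of its probe sets (-0.080) or against SKR6 (-0.19, adjusted p = 0.0779). Of 15 ERBB receptors and ligands 2 rose and 3 fell (camera adjusted p = 0.693), and betacellulin (BTC) fell by 1.20, although it did not differ detectably from SKR6 (0.28, adjusted p = 0.210).

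Stress and lipid genes were also higher with active p65. Among 27 amino-acid and unfolded-protein stress genes 15 rose and 1 fell (camera adjusted p = 6.83e-06; adjusted p = 0.700 with an estimated correlation), with the cystine transporter SLC7A11 higher by 1.98, PPP1R15A by 0.76 and HERPUD1 by 0.72. The transporter subunit SLC3A2, named after its value was seen, fell by 0.63. Among 15 genes of fatty acid synthesis 7 rose and 0 fell (camera adjusted p = 2.84e-05), and this list kept its call with an estimated correlation (adjusted p = 0.0316); the desaturase SCD rose by 1.00 and FASN by 0.86. Among 16 genes of cholesterol synthesis 8 rose and 1 fell (camera adjusted p = 0.000628; adjusted p = 0.365 with an estimated correlation), and INSIG1 rose by 1.88 and STARD4 by 1.70. SC5D, named after its value was seen, fell by 0.84. Adjusted over each list alone, the risen and fallen members were 20 and 2 for stress, 8 and 0 for fatty acids, and 9 and 1 for cholesterol.

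Immune and metabolic genes were also among the called lists. Of 33 interferon-stimulated genes 12 rose and 0 fell (median 0.46, camera adjusted p = 0.000103; adjusted p = 0.700 with an estimated correlation, 0.102 with fry), with IFITM1 higher by 2.72 and OAS1 by 2.19. Of 22 antigen presentation genes 6 rose and 0 fell (camera adjusted p = 0.0122; adjusted p = 0.700 with an estimated correlation, 0.123 with fry), with the immunoproteasome subunits PSMB8 and PSMB10 higher by 0.89 and 0.84. Hypoxia and glycolysis genes (12 rose, 3 fell of 28) had camera adjusted p = 0.0223 and adjusted p = 0.152 with an estimated correlation, with ADM higher by 0.91 and PFKFB3 lower, at -1.35, although higher than in SKR6 by 0.76 (adjusted p = 0.00656). Respiratory chain genes (8 rose, 1 fell of 22) had camera adjusted p = 0.00370 and adjusted p = 0.700 with an estimated correlation, with UQCRC1 higher by 0.51 and UQCRC2 by 0.45. Against SKR6 neither UQCRC1 (0.17, adjusted p = 0.261) nor UQCRC2 (0.14, adjusted p = 0.0576) was called. Adjusted over the list alone, 13 interferon-stimulated, 6 antigen presentation, 13 hypoxia and 10 respiratory genes rose.

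Basal, transporter and lysosome genes were lower in SKR6CA than in SKR6-Vector. Of 13 basal genes 0 rose and 7 fell (camera adjusted p = 7.30e-05; adjusted p = 0.152 with an estimated correlation), and CAV1, encoding caveolin, fell by 3.38 and the kinase MYLK by 2.35. Of 21 drug transporter and metabolism genes 3 rose and 9 fell (camera adjusted p = 0.0127; adjusted p = 0.152 with an estimated correlation). The cytochromes CYP1A1 and CYP1B1 fell by 4.02 and by 2.18; the 3 that rose were ABCC2, GSTM1 and ABCC1, named after their values were seen. Of 24 lysosome and autophagy genes 2 rose and 11 fell (camera adjusted p = 0.0202; adjusted p = 0.700 with an estimated correlation), among them the lysosomal channel MCOLN1, which fell by 0.82, while the cathepsin CTSZ rose by 1.67. Adjusted over each list alone, 7, 9 and 11 members fell. With the filter on low values the subunit (adjusted p = 0.0802), antigen presentation (0.0645), hypoxia (0.0507) and lysosome (0.0811) lists lost their calls, and without _x_at and _s_at probe sets the hypoxia (0.0666), transporter (0.143) and lysosome (0.0718) lists did.

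Over all 19775 genes, limma called 5251 at an adjusted p under 0.05, of which 2305 were higher and 2946 lower in SKR6CA. Of these, 213 were higher and 355 lower by at least 1 on the log2 scale. With median centring 56.2% of the calls were higher, against 43.9% as deposited, while the median over all genes moved by under 0.1. The arrays of both groups did not overlap for 45.5% of genes, where chance gives 10%. Beside the NF-kB genes, the largest rises were in the aminophospholipid transporter ATP11A (3.76, but 0.19 on its probe set outside the _s_at kind), DNAAF1 (3.56), the phosphatase PTPRB (3.50), BPIFA4P (3.48), BHLHA15 (3.29), FBLN5 (3.16) and the collagenases MMP13 (3.15) and MMP1 (2.96). The largest falls were in OLFM4 (-6.35), SCIN (-5.40), GABBR2 (-4.26), FBN2 (-4.11) and CYP1A1 (-4.02).

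The choice of control mattered for this comparison. Against SKR6, NF-kB target genes were again higher in SKR6CA: 21 rose, 1 fell and the median was 0.63 (camera adjusted p = 1.81e-08; adjusted p = 0.366 with an estimated correlation). The stress, fatty acid, cholesterol, antigen presentation and NF-kB subunit lists were called higher against both controls. Of these, against SKR6, the fatty acid list kept its call with an estimated correlation (adjusted p = 0.0156), while cholesterol was at 0.132 and the other 3 lists at 0.366. Against SKR6, 5 further lists were called, and 0 of these calls were kept with an estimated correlation. Proliferation genes were lower, with 22 of 38 fallen and 0 risen (median -0.42, camera adjusted p = 2.45e-08; adjusted p = 0.533 with an estimated correlation). FOXO-linked (camera adjusted p = 0.00612), cell-cycle inhibitor (0.0125) and mesenchymal (0.0160) genes were higher, each at 0.132 with an estimated correlation, and so were cytokine and chemokine genes (0.0338; 0.740 with an estimated correlation). IFITM1, OAS1 and MYLK, called against SKR6-Vector, did not differ detectably from SKR6 (0.067, 0.23 and -0.13). CAV1, which fell against SKR6-Vector, was higher than in SKR6 by 1.45. Of the largest falls, OLFM4 and GABBR2 were higher than in SKR6, by 1.76 and 1.25 (adjusted p = 3.86e-06), FBN2 did not differ detectably (0.31), and SCIN was lower by less, at -0.79. Basal, interferon-stimulated, lysosome and respiratory lists had medians of 0.041, 0.060, 0.0042 and -0.070 against SKR6, with tested directions opposite to those against SKR6-Vector and no call; the interferon test ran below 0 while its median lay above 0. The hypoxia and transporter lists also lost their calls against SKR6, although CYP1A1 and CYP1B1 were lower than in SKR6 too, at -3.60 and -2.05. Of the 2305 genes higher against SKR6-Vector, 942 (40.9%) were higher against SKR6 as well and 211 were lower. Of the 2946 lower genes, 1323 (44.9%) were lower against SKR6 as well and 261 were higher. Among genes that differed from SKR6-Vector by at least 1, 151 of 213 higher and 192 of 355 lower genes were called in the same direction against SKR6.

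The comparison of SKR6LR with SKR6 asked how the lapatinib-selected line differed from the line it came from. Single luminal, basal, interferon-induced and cytokine genes differed by large amounts. AGR2, a secretory protein of luminal cells, fell from 13.34 ± 0.01 to 6.26 ± 0.70 (mean ± SD, n = 3 and 3), a log2 difference of -7.08 (SE 0.239, adjusted p = 6.53e-11). CAV1 rose from 6.28 ± 0.20 to 13.92 ± 0.05, by 7.64 (SE 0.087, adjusted p = 6.15e-15). The interferon-induced MX1 rose by 6.97 (SE 0.303, adjusted p = 7.25e-10) and the cytokine IL6 by 6.01 (SE 0.280, adjusted p = 1.42e-09).

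ERBB receptors changed in opposite directions. ERBB2 fell from 13.83 ± 0.02 to 12.45 ± 0.09 (-1.38, SE 0.057, adjusted p = 4.28e-10) and ERBB3 by 0.84 (adjusted p = 5.56e-07), while EGFR rose from 8.58 ± 0.08 to 13.26 ± 0.05 (4.68, SE 0.064, adjusted p = 2.50e-14). The ligand EGF fell by 5.08 and LRIG1, a negative regulator of ERBB receptors, by 3.94, while the EGFR ligand HBEGF rose by 2.16. Of 15 ERBB receptors and ligands 4 rose and 6 fell (camera adjusted p = 0.871). Of 15 genes of the 17q12 amplicon, which holds ERBB2, 13 fell and 1 rose (camera adjusted p = 0.00306; adjusted p = 0.388 with an estimated correlation). GRB7 fell by 1.28 and STARD3 by 1.02, and the gene that rose was the lymphoid transcription factor IKZF3 (2.64). The same numbers passed when adjusted over the list alone.

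**Figure D3:**
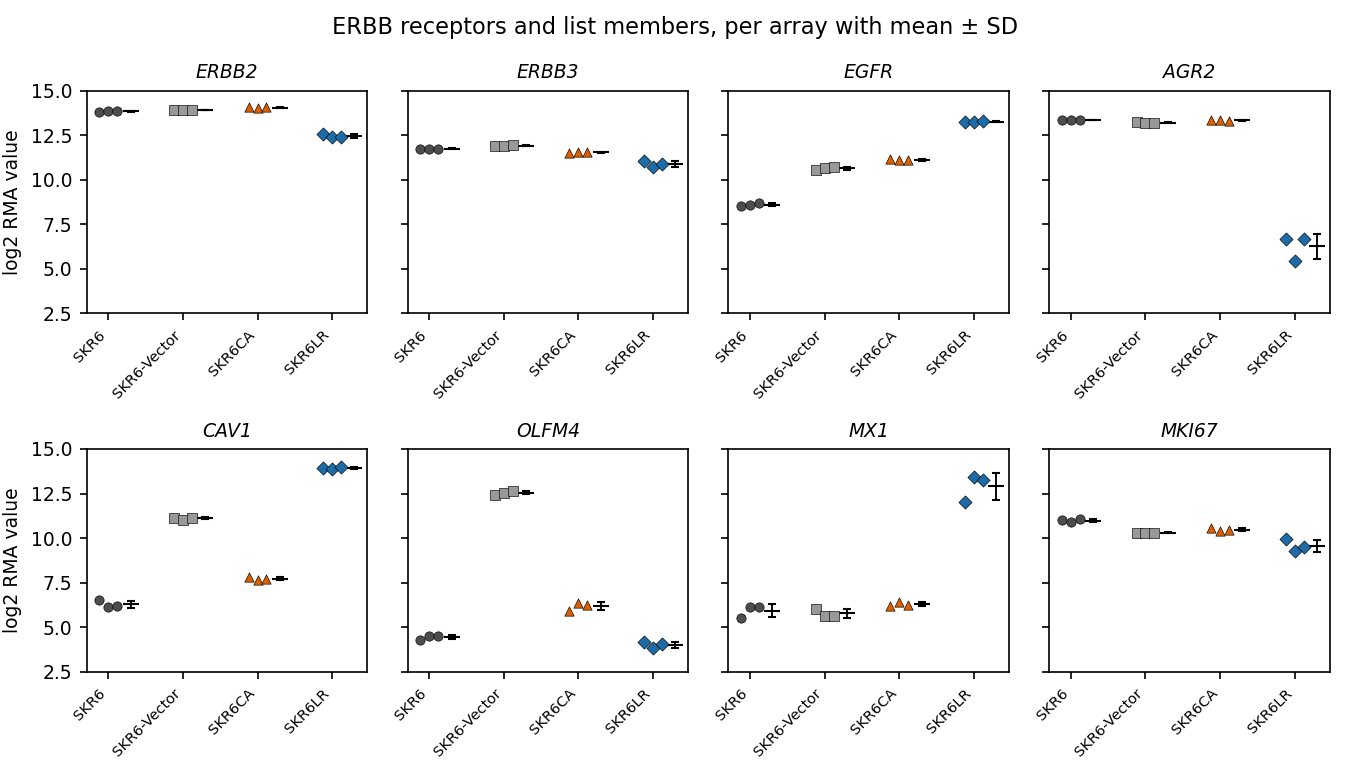
ERBB2, ERBB3, EGFR and 5 further genes on the 12 arrays; points are single arrays in log2 RMA values, and the bars beside them give the mean ± SD of the 3 replicates. ERBB2 and AGR2 are lowest in SKR6LR, CAV1 and EGFR are highest there and also higher in SKR6-Vector than in SKR6, and OLFM4 is high in SKR6-Vector, at 12.54, against 4.43 in SKR6.

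Cell identity genes shifted by large amounts. Of 21 luminal and oestrogen-receptor genes 14 fell and 4 rose (median -0.94, camera adjusted p = 0.0117; adjusted p = 0.140 with an estimated correlation). MLPH fell by 6.05 and the transcription factor SPDEF by 3.41, while the 4 that rose were GATA3, STC2, KRT18 and KRT8, named after their values were seen. Of 13 basal genes 11 rose and 1 fell (median 3.65, camera adjusted p = 2.06e-07; adjusted p = 0.140 with an estimated correlation). Smooth muscle actin ACTA2 rose by 7.13 and the integrin ITGA6 by 6.60, and KRT15 fell by 1.41. Of 15 stem-cell-associated genes 8 rose and 3 fell (camera adjusted p = 0.0198; adjusted p = 0.421 with an estimated correlation), with the efflux transporter ABCG2 higher by 7.40, CD44 by 1.83 and SOX9 lower, at -2.37. Adjusted over each list alone, the same numbers of members passed in these 3 lists.

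Interferon and NF-kB genes were higher in SKR6LR. Of 33 interferon-stimulated genes 30 rose and 0 fell (median 3.53, camera adjusted p = 5.65e-15; adjusted p = 0.388 with an estimated correlation), with IFI44L higher by 7.13, HERC5 by 6.69 and XAF1 by 6.47. It was 30 and 1 adjusted over the list alone. Of 22 antigen presentation genes 18 rose and 1 fell (camera adjusted p = 2.33e-07; adjusted p = 0.388 with an estimated correlation), with PSMB9 higher by 4.11 and the peptide transporter TAP1 by 2.93. HLA-DMA, named after its value was seen, fell by 1.85, and 18 and 1 also passed adjusted over the list alone. Of 42 NF-kB target genes 26 rose and 3 fell (median 0.78, camera adjusted p = 8.49e-07; adjusted p = 0.468 with an estimated correlation), or 27 and 3 adjusted over the list alone. CCL5 rose by 6.65, CCL2 by 4.96 and TNFAIP3 by 3.57; MMP9, IER3 and CXCL1, named after their values were seen, fell. CFB had a difference of 4.46 on its _s_at probe set and -0.19, not called, on the other. Of 37 cytokine and chemokine genes 18 rose and 3 fell (camera adjusted p = 0.000227; adjusted p = 0.491 with an estimated correlation), likewise 18 and 3 adjusted over the list alone, with CXCL8 higher by 3.75.

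NF-kB subunits and upstream regulators changed by less. Of 22 members 10 rose and 3 fell (camera adjusted p = 0.0443; adjusted p = 0.628 with an estimated correlation), and the call was lost without SKR6 replicate 1 (adjusted p = 0.0529) or without SKR6LR replicate 2 (adjusted p = 0.119), and against SKR6-Vector as the other control (median 0.11). RELB rose by 1.79, MAP3K14, the kinase of the alternative NF-kB pathway, by 1.12 and MAP3K7 by 1.01. RELA rose by 0.37 (adjusted p = 0.00464), but had 0.14 and was not called against SKR6-Vector. On the second RELA probe set the difference from SKR6 was 0.26 and not called (adjusted p = 0.0639 over all probe sets). The 3 members that fell were CYLD, TAB2 and IKBKB, named after their values were seen. Adjusted over the list alone, 10 rose and 4 fell.

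Genes of cell death again moved in both directions. Of 15 anti-apoptotic genes 5 rose and 4 fell (camera adjusted p = 0.448), or 5 and 5 adjusted over the list alone. TNFAIP3, CFLAR (1.55), GADD45B (1.37, but 0.14 and not called outside _s_at probe sets), MCL1 and XIAP rose, and BIRC5 fell by 1.70. Of 22 pro-apoptotic genes 7 rose and 10 fell (camera adjusted p = 0.612), with PMAIP1 higher by 4.30 and the caspase CASP6, BID and APAF1 lower, at -2.74, -2.13 and -1.81.

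Growth and energy genes were lower. Of 38 proliferation genes 35 fell and 0 rose (median -0.98, camera adjusted p = 1.85e-07; adjusted p = 0.491 with an estimated correlation), with RRM2 at -2.25 and FOXM1 at -1.89. Of 22 respiratory chain genes all 22 fell (median -0.50, camera adjusted p = 1.68e-06; adjusted p = 0.388 with an estimated correlation), with NDUFA9 at -1.23. Of 18 cell-cycle inhibitor and p53 target genes 10 rose and 5 fell (camera adjusted p = 0.0198; adjusted p = 0.237 with an estimated correlation), with CDKN2B higher by 4.23, although it did not differ from SKR6-Vector (-0.24, adjusted p = 0.106). CDKN1C rose by 3.18, and CDKN1B, named after its value was seen, fell by 2.06. Of 16 cholesterol synthesis genes 13 rose and 1 fell (median 1.13, camera adjusted p = 2.33e-07; adjusted p = 0.140 with an estimated correlation), with STARD4 higher by 4.57 and INSIG1 by 3.70, and EBP lower, at -0.86. Adjusted over the list alone, 36 proliferation genes fell, and the numbers of the other 3 lists were the same. With the filter on low values the luminal (adjusted p = 0.0686), cell-cycle inhibitor (0.0831) and NF-kB subunit (0.0913) lists lost their calls, and without _x_at and _s_at probe sets the stem-cell-associated (0.0585), cell-cycle inhibitor (0.208) and NF-kB subunit (0.142) lists did. Against SKR6-Vector the stem-cell-associated (median 0.084, adjusted p = 0.337) and cell-cycle inhibitor (median 0.013, adjusted p = 0.337) lists were not called.

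Over all genes, limma called 10345 of 19775, with 4223 higher and 6122 lower; 1498 were higher and 1583 lower by at least 1 on the log2 scale. With cyclic loess scaling 52.3% of the calls were higher, against 40.8% as deposited. The arrays of both groups did not overlap for 57.9% of genes, against 10% by chance. The largest rises were in the protease ADAMTS1 (9.03), SRGN (8.21), CAPN6 (8.16), TCEAL9 (8.14) and the matrix protein SPARC (8.11), and the largest falls in SELENOP (-8.69), the long noncoding RNA DSCAM-AS1 (-8.37), SCGB2A2 (-8.30), TRPS1 (-7.97) and AZGP1 (-7.25). In data simulated with few changed genes and the wider spread of the SKR6LR replicates, 73 of 259 calls in this comparison (28.2%) were of unchanged genes. The growth protocol says that cells it calls SKLR were kept in 0.2 µM lapatinib; whether SKR6LR is meant, and whether the drug was present in the 48 hours before RNA was taken, is not settled by the labels.

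**Figure D4:**
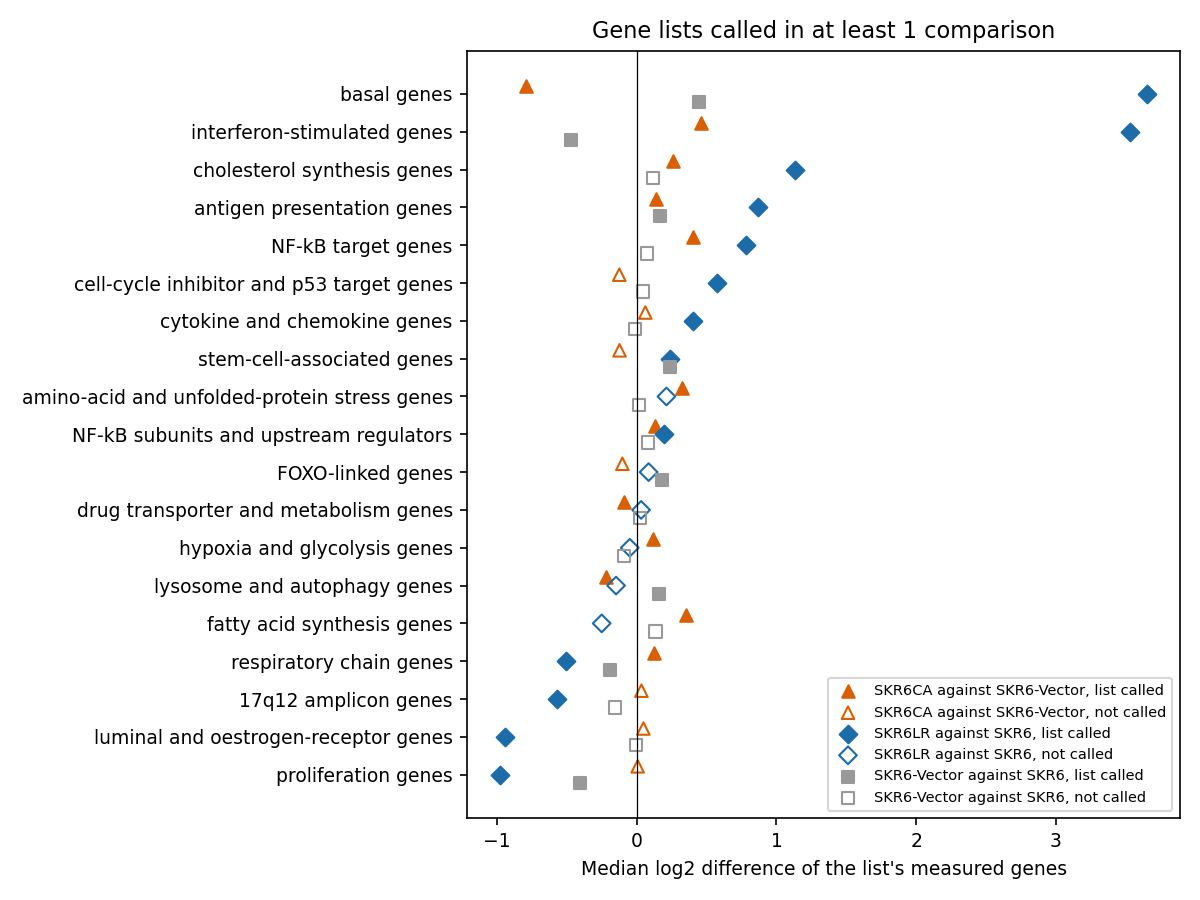
Median log2 difference of the measured genes of each list called in at least 1 comparison, with SKR6CA against SKR6-Vector as triangles, SKR6LR against SKR6 as diamonds and SKR6-Vector against SKR6 as squares; filled symbols mark lists called by camera with its preset correlation. Basal genes have medians of 3.65 in SKR6LR, -0.79 in SKR6CA and 0.44 in SKR6-Vector.

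The comparison of SKR6-Vector with SKR6 measured what came with the empty vector and puromycin selection. The control line differed from its parent by large amounts in some genes. OLFM4, an epithelial stem cell gene, rose from 4.43 ± 0.12 to 12.54 ± 0.09 (mean ± SD, n = 3 and 3), by 8.11 (SE 0.118, adjusted p = 6.92e-13). GABBR2 rose by 5.52, BMP7 by 5.18, CAV1 by 4.83 and SCIN by 4.61. IFI27 fell by 4.03, IGFBP2 by 3.39, GATA5 by 3.19, IFI6 by 2.94 and the glutamate transporter SLC1A1 by 2.93. EGFR rose by 2.06 (adjusted p = 5.49e-10), and ERBB2 differed by 0.091 (adjusted p = 0.299), ERBB3 by 0.18 (adjusted p = 0.0998) and RELA by 0.23 (adjusted p = 0.0924). Without SKR6LR replicate 1, which lowers the shared estimate of spread, ERBB3 and RELA passed (adjusted p = 0.0208 and 0.0179), and likewise without SKR6LR replicate 2 (0.0303 and 0.0166).

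Proliferation genes fell in SKR6-Vector for 22 of 38 members, with 0 that rose (median -0.40, camera adjusted p = 6.41e-08; adjusted p = 0.593 with an estimated correlation), and 27 fell adjusted over the list alone. MCM2 fell by 0.82 and MKI67, the Ki-67 gene, by 0.70. Respiratory chain genes fell for 13 of 22 (camera adjusted p = 7.27e-05; adjusted p = 0.593 with an estimated correlation) and interferon-stimulated genes for 14 of 33, with IFITM1 at -2.65 (camera adjusted p = 0.000103; adjusted p = 0.642 with an estimated correlation). Basal genes rose for 6 of 13, with ACTA2 higher by 2.16 and MYLK by 2.22 (camera adjusted p = 6.40e-05; adjusted p = 0.374 with an estimated correlation). Lysosome and autophagy genes rose for 9 of 24 and fell for 2, with GPNMB higher by 2.27 (camera adjusted p = 0.0159; adjusted p = 0.593 with an estimated correlation). FOXO-linked genes rose for 8 of 19 and fell for 2, with SESN3 higher by 1.51 and FOXO1 by 1.06 (camera adjusted p = 0.0171; adjusted p = 0.374 with an estimated correlation). Stem-cell-associated genes rose for 7 of 15 and fell for 3, with ALDH1A1 higher by 2.66 (camera adjusted p = 0.0301; adjusted p = 0.593 with an estimated correlation). Antigen presentation genes rose for 6 of 22, with PSMB9 higher by 1.13 (camera adjusted p = 0.0301; adjusted p = 0.642 with an estimated correlation, 0.170 with fry). Adjusted over each list alone, 13 respiratory and 14 interferon-stimulated genes fell and 6 basal, 9 lysosome, 9 FOXO-linked, 7 stem-cell-associated and 6 antigen presentation genes rose. Without _x_at and _s_at probe sets the FOXO-linked (adjusted p = 0.150), stem-cell-associated (0.298) and antigen presentation (0.181) lists lost their calls. The filter on low values ended the FOXO-linked (0.0767) and stem-cell-associated (0.137) calls, and the mean of probe sets the antigen presentation call (0.0748).

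NF-kB target genes changed little with the vector. Of 42 members 5 rose and 1 fell (camera adjusted p = 0.310), and the largest rises were in LCN2 (2.19) and NFKBIZ (1.94). Of 15 anti-apoptotic genes 2 rose and 0 fell (camera adjusted p = 0.428; median -0.015, but mean 0.037 and tested direction above 0); they were GADD45B (0.68, but 0.060 and not called outside _s_at probe sets) and MCL1 (0.34). Of 22 pro-apoptotic genes 5 rose and 5 fell (camera adjusted p = 0.503), with BMF higher by 1.30 and TNFRSF10B lower, at -1.08. Of 15 ERBB receptors and ligands 2 rose and 3 fell (camera adjusted p = 0.319), and BTC rose by 1.49. Over all genes limma called 5073, with 2418 higher and 2655 lower, or 47.7% higher, against 55.0% with cyclic loess and 42.3% with median centring; 377 were higher and 150 lower by at least 1 on the log2 scale. The arrays of both groups did not overlap for 48.2% of genes, against 10% by chance.

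**Figure D5:**
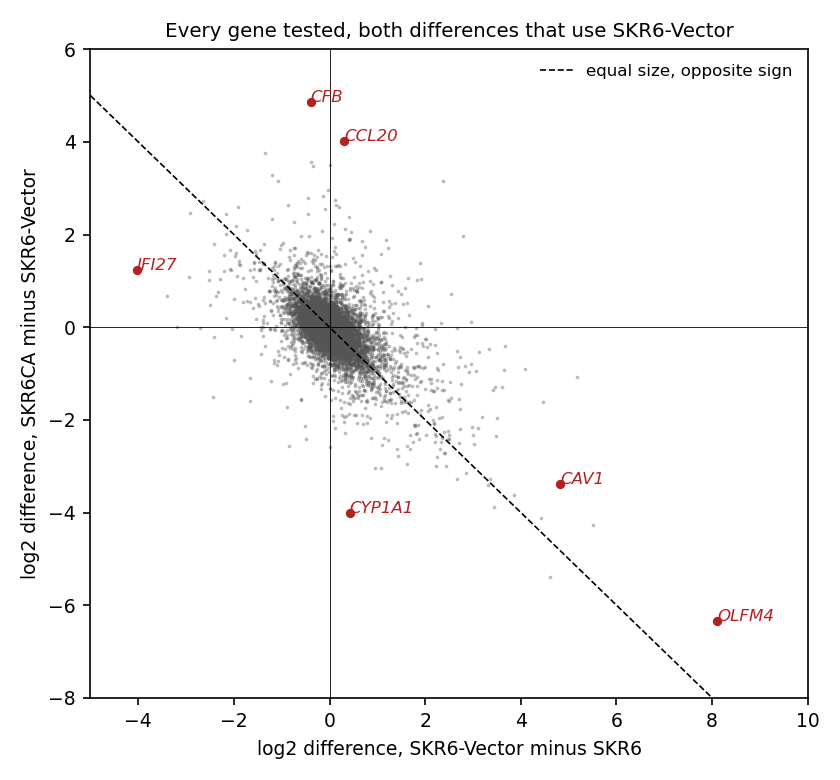
Log2 difference of SKR6CA minus SKR6-Vector against that of SKR6-Vector minus SKR6 for the 19775 genes tested; each point is 1 gene, 6 genes are named, and the dashed line marks equal size with opposite sign. OLFM4 (8.11 and -6.35) and CAV1 (4.83 and -3.38) lie toward that line, and CCL20 (0.30 and 4.02) and CYP1A1 (0.42 and -4.02) lie off it; both differences use the SKR6-Vector arrays.

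The effects of active p65 and of lapatinib selection were also set against each other, with SKR6CA minus SKR6-Vector and SKR6LR minus SKR6, which share no array. TNFAIP3, GBP1 (2.74 and 4.50) and IFITM1 (2.72 and 2.96) rose in both, but IFITM1 in SKR6CA did not differ detectably from SKR6 (0.067, adjusted p = 0.787). CAV1, EDIL3 and IGFBP3 were lower in SKR6CA than in SKR6-Vector and rose in SKR6LR, but none of the 3 was lower in SKR6CA than in SKR6 (1.45, 0.070 and 0.23). Of 42 NF-kB target genes 14 rose in both comparisons, where independent calls would give 11.8, 1 fell in both and 1 moved in opposite directions. Of all genes, 2182 were called in both in the same direction, where independent lists would share 1404, and 1861 in opposite directions, where they would share 1343. Across genes, which are not independent replicates, Pearson's r of both sets of differences was 0.037 and Spearman's rho 0.062.

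The test of the difference between both effects called 8972 genes, with 5056 values above 0 and 3916 below, and it called 12 lists, 0 of them with an estimated correlation. With cyclic loess scaling 46.1% of these calls lay above 0, against 56.4% as deposited. NF-kB target genes differed by a median of -0.31 (camera adjusted p = 0.0317, or 0.790 with an estimated correlation). They were higher with active p65 (median 0.40) and in SKR6LR (median 0.78), so the value marks a smaller rise with active p65. The call was lost without SKR6CA replicate 1 (median -0.24, adjusted p = 0.0564) and without SKR6LR replicate 2 (median -0.22, adjusted p = 0.126). It was also lost with the filter on low values (adjusted p = 0.101), with the mean of probe sets (0.0778) and without _x_at and _s_at probe sets, where the median was 0.026 (adjusted p = 0.623), and with fry (0.0758). Within that list CCL20 differed by 4.01 and CCL5 by -6.48. Basal genes differed by a median of -3.78 (camera adjusted p = 4.14e-10; adjusted p = 0.0626 with an estimated correlation) and interferon-stimulated genes by -3.06 (camera adjusted p = 4.14e-10; adjusted p = 0.380 with an estimated correlation). Luminal genes differed by 1.05 (camera adjusted p = 0.00624; adjusted p = 0.131 with an estimated correlation), proliferation genes by 0.99 (camera adjusted p = 5.72e-07; adjusted p = 0.529 with an estimated correlation) and 17q12 genes by 0.37 (camera adjusted p = 0.00858; adjusted p = 0.349 with an estimated correlation). The 17q12 call was also lost with the filter on low values (adjusted p = 0.0591) and without _x_at and _s_at probe sets (0.0719). The cell-cycle inhibitor call was lost under both (median -0.43, adjusted p = 0.0591, and -0.12, 0.145) and the cytokine call without these probe sets (-0.091, 0.0638). ERBB2 differed by 1.50 (adjusted p = 9.45e-09) and EGFR by -4.22 (adjusted p = 2.63e-12).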

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

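The tests of the SKR6-Vector pattern and of degraded RNA, mixture and replacement in SKR6LR were chosen after the results they bear on had been seen; the splits of the arrays and the test of neighbouring genes were not.

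Several gene lists differed between SKR6CA minus SKR6-Vector (called the p65 effect) and SKR6LR minus SKR6 (called the lapatinib effect), by camera's test of the difference. Of these 12 calls 0 were kept with an estimated correlation. Median differences (p65 effect minus lapatinib effect) were -0.31 for NF-kB target genes, 0.37 for 17q12 amplicon genes, 1.05 for luminal genes, -3.78 for basal genes, -0.40 for stem-cell-associated genes, -3.06 for interferon-stimulated genes, -0.84 for antigen presentation, -0.39 for cytokines, 0.99 for proliferation, -0.59 for cell-cycle inhibitors and p53 targets, -0.83 for cholesterol synthesis and 0.63 for the respiratory chain. Adjusted p with an estimated correlation was 0.305 for the stem-cell-associated and respiratory lists, 0.380 for antigen presentation, 0.631 for cytokines, 0.208 for cell-cycle inhibitors and 0.264 for cholesterol synthesis; without _x_at and _s_at probe sets the NF-kB target (0.026), 17q12 (0.35), cytokine (-0.091) and cell-cycle inhibitor (-0.12) medians were no longer called. In 100 joint splits of the arrays, 10 gave 12 or more called lists, the real one included (highest other 15), so chance was not excluded for the number of lists. For the 8972 called genes only the real split gave as many (1 of 100, highest other 6977). Joint splits that mix a pair of lines remove its effect, while those that leave a pair whole keep it. Such kept effects can raise the counts of the other splits. Neither count therefore decides whether both effects differ from each other, and the list count does not measure chance alone.

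Single genes differed by the same test. The differences were -11.02 for CAV1, -10.56 for EDIL3, -9.74 for CAPN6, -9.08 for CAV2, -9.00 for ADAMTS1, 8.13 for DSCAM-AS1, 7.73 for AZGP1, 7.45 for TRPS1, 7.23 for KITLG and 7.21 for AGR2. Among the genes named in every comparison they were -4.22 for EGFR, 1.50 for ERBB2, 0.47 for ERBB3 and -0.43 for RELA. Part of the differences rests on SKR6-Vector, which exceeded SKR6 in CAV1 (4.83), CAV2 (3.46), EDIL3 (3.36) and CAPN6 (1.76); SKR6CA was not lower than SKR6 in these genes (1.45, 2.17, 0.070 and 0.18). The RELA difference fell to -0.25 and was not called with the mean of its probe sets.

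SKR6CA differed from SKR6-Vector in many genes in which SKR6-Vector itself differed from SKR6. Across genes the covariance of both differences was -0.0875, while error in the shared SKR6-Vector arrays alone gave -0.00614 on average and -0.00669 at most extreme in 100 simulations, which argues against that error as the whole cause. The correlation was -0.576, against -0.500 on average and -0.522 at most extreme in the simulations. Any true difference of SKR6-Vector from the other lines enters both comparisons with opposite signs, so neither value tells which line changed. Over the 527 genes that differed between SKR6-Vector and SKR6 by at least 1, the median share of that difference also found in SKR6CA minus SKR6 was 0.396, and 309 genes (58.6%) had a share under 0.5. Lines that each changed on their own by like amounts would give a share near 0.5, so 0.396 sets SKR6-Vector apart only weakly. A candidate explanation is that the SKR6-Vector line changed on its own and SKR6CA did not follow, for instance through growth from few transduced cells. That active p65 reversed changes brought by vector and selection stays open as well and was not tested.

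The SKR6LR arrays lay far from the other lines. A mixture of other cells with many unchanged SKR6 cells is argued against by 26 genes that were lower by at least 5 on the log2 scale. Such falls would leave at most 3.125% of the original transcripts. A mixture of other cells with changed SKR6 cells is not tested by these falls. Degraded RNA as the whole cause is argued against by the first principal component, on which SKR6LR minus SKR6 was 143 before and 132 (SE 4.76) after adjustment for the 3′ minus 5′ differences of actin and GAPDH, although 1 of the 3 SKR6LR arrays exceeded all other lines on both controls. With both differences as covariates, 6296 genes were called for SKR6LR against SKR6, against 10345 without them. Of the 6296, 5824 were also called in the same direction without the covariates. For the covariates themselves 0 genes were called with actin and 0 with GAPDH. The added terms also cost precision, so the lower count does not by itself measure an effect of RNA quality. Replacement by cells without the 17q12 amplicon stays open. Its core genes had a median difference of -1.02, and how far they would fall without the amplicon was not measured here. By level in SKR6LR they stood between the 70.4 (GRB7) and 98.6 (MIEN1) percentile of all genes, with ERBB2 at 97.0. In SKR6 they stood between 82.8 (GRB7) and 99.4 (MIEN1). Lapatinib selection, the drug's presence during culture and replacement by another HER2-amplified line stay open as well and were not tested.

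Neighbouring genes shifted together. Among 9875 expressed genes in chromosomal order, 111 of 8748 windows of 50 genes had a median beyond every window of 100 shuffled orders in SKR6LR against SKR6, 198 in SKR6-Vector against SKR6 and 160 in SKR6CA against SKR6-Vector. The longest block in SKR6LR ran from MPHOSPH8 to LIG4 on chromosome 13, with 149 genes and a median of -0.72, and in SKR6-Vector blocks ran from MTFR1L to YBX1 (-0.26) and from DOK1 to R3HDM1 (-0.27). The block from MTHFD2 to MGAT5 was higher by 0.26 in SKR6CA than in SKR6-Vector. It lies on chromosome 2, as does the block from DOK1 to R3HDM1. Both comparisons use the SKR6-Vector arrays, so a shift in SKR6-Vector alone can show in both, with opposite signs. A candidate explanation is that the lines differ in copy number, and shared regulation of neighbouring genes stays open, since DNA was not analysed here.

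The counts of each comparison of 3 with 3 arrays can be set only against 10 splits, too few for a share under 0.05. In SKR6CA against SKR6-Vector the real split gave 5251 genes and 12 lists, and the highest other 0 genes and 6 lists (1 of 10 splits as large in both). In SKR6LR against SKR6 it gave 10345 genes (1 of 10, highest other 0) and 13 lists (3 of 10, highest other 14). In SKR6-Vector against SKR6 it gave 5073 genes (1 of 10, highest other 0) and 8 lists (1 of 10, highest other 4). For genes called in both main comparisons, 1 of 100 joint splits gave as many in the same direction (2182, highest other 0) and 1 of 100 in opposite directions (1861, highest other 0). These splits do not decide whether the overlap is larger than chance, because no gene was called in either single comparison under any other grouping of its 6 arrays.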

How the results depend on the processing

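One weight per group was added after the data were seen; the other alternatives were fixed before. Over all alternatives, 6129 values of named genes and 1314 of lists kept direction and side of the threshold; 54 and 85 lost the call, 16 and 5 gained it and 26 and 4 reversed. Leaving out each array gave 4294 to 6236 called genes for SKR6CA against SKR6-Vector (560 to 571 at 1 or more, 12 to 13 lists), 9524 to 10533 for SKR6LR against SKR6 (2951 to 3247, 12 to 14 lists), 3981 to 6105 for SKR6-Vector against SKR6 (513 to 528, 8 to 9 lists) and 8407 to 9511 for the difference of both effects (3187 to 3438, 11 to 13 lists). It gave 1788 to 2587 genes called in both in the same direction, 1529 to 2235 in opposite directions and correlations of both effects of 0.028 to 0.043. The correlation was 0.031 with array weights, 0.044 with the filter on low values and 0.057 with the mean of probe sets. Array weights called 7641 genes for SKR6-Vector against SKR6. Every probe set, a larger number of tests, gave 10563 calls (1162 at 1 or more), 24013 (6691) and 9407 (974) in the 3 comparisons. With an estimated correlation 1, 0, 0 and 0 lists were called; fry called 12, 29, 18 and 21. Fry ended the calls of the NF-kB subunit (adjusted p = 0.0537), interferon-stimulated (0.102) and antigen presentation (0.123) lists in SKR6CA, of antigen presentation in SKR6-Vector (0.170) and of NF-kB targets in the difference of both effects (0.0758). In SKR6LR it called the anti-apoptotic list higher (0.0219) and the pro-apoptotic (9.47e-06) and ERBB (0.00130) lists lower, unlike camera. It likewise called the ERBB list higher in SKR6-Vector (0.000457) and the pro-apoptotic list above 0 in the difference of both effects (0.000446). Group weights called 9102 genes for SKR6LR against SKR6, 9076 of them among the 10345. They called more genes in the comparisons without SKR6LR. The counts were 6857 against 5251 for SKR6CA against SKR6-Vector and 7579 against 5073 for SKR6-Vector against SKR6. In simulated data these weights also raised the false share of both, as given above. The replicate numbers did not pair the arrays: over 18 pairs of same-numbered arrays, correlations of deviations ran from -0.034 to 0.095, and 5 of 12 arrays were closest to their own number. With the replicate number as a block 5105, 10244, 4825 and 8832 genes were called, 2109 in both in the same direction and 1805 in opposite ones, with the same 12, 13, 8 and 12 list counts, and of the named genes CHAC1 alone lost its call.

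Reversed values were as follows, and their cause was not tested. With the mean of probe sets CFLAR had -0.000479 in SKR6CA. Without _x_at and _s_at probe sets SKR6CA gave CASP8 0.13, IDI1 -0.49 and NDUFS1 -0.020, SKR6LR gave CFB -0.19, SKR6-Vector gave BOK -0.12, and the difference of effects gave SC5D 0.0090. Against SKR6 as the other control, SKR6CA gave ABCC4 0.33, ACTA2 0.78, BMF 0.21, BTC 0.28, CAV1 1.45, COX5B -0.0046, EDIL3 0.070, FBN2 0.31, GABBR2 1.25, GPNMB 1.34, HBEGF -0.0040, IFI27 -2.80, IGFBP3 0.23, OLFM4 1.76, PFKFB3 0.76 and TNFRSF10B -0.092, and list medians of 0.041 (basal), 0.060 (interferon-stimulated), 0.0042 (lysosome) and -0.070 (respiratory chain). Against SKR6-Vector, SKR6LR gave CDKN2B -0.24, FBN2 -1.25 and GABBR2 -1.73. No detection calls come with the values, so differences between genes near the lowest values are limited by background.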

Other observations

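No test in this part was used to choose an explanation; the lists were fixed before the data were examined, and their members named here were chosen after their values were seen.

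Growth factor signalling genes moved in both directions. Of 22 MAPK pathway output genes 4 rose and 8 fell in SKR6CA against SKR6-Vector (camera adjusted p = 0.827), with DUSP6, a phosphatase of ERK, lower, at -2.06, and EGR1 higher by 1.38. In SKR6LR against SKR6, 11 rose and 7 fell (camera adjusted p = 0.0572), with EPHA4 higher by 4.31 and SPRY1 at -1.63. Of 18 other receptor tyrosine kinases 4 rose and 4 fell in SKR6CA (camera adjusted p = 0.970, tested below 0 with a mean of 0.010 above it) and 7 rose and 4 fell in SKR6LR (camera adjusted p = 0.197, with a median of -0.066 below 0 and a mean of 0.48 above it). MERTK rose by 3.09, MET by 2.73 and FGFR2 by 2.69 in SKR6LR. FOXO-linked genes were not called in SKR6CA (5 rose, 8 fell of 19, adjusted p = 0.827) or in SKR6LR (9 rose, 7 fell, adjusted p = 0.341), where IRS2 rose by 3.11 and CDKN1B fell by 2.06.

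Metabolic and structural lists that camera did not call held large single changes. Of 15 fatty acid synthesis genes 5 rose and 8 fell in SKR6LR (camera adjusted p = 0.640), with SCD higher by 1.94 and FASN at -1.08. Hypoxia and glycolysis genes in SKR6LR (10 rose, 12 fell of 28, adjusted p = 0.650) had a median of -0.050, but a mean of 0.27 and a tested direction above 0, with SLC2A3, a glucose transporter, higher by 6.28. NRF2 targets (5 rose, 9 fell of 20, adjusted p = 0.818) had a median of -0.10 and a tested direction below 0, but a mean of 0.029, with HMOX1 higher by 2.79 and NQO1 at -1.81. Amino-acid and unfolded-protein stress genes in SKR6LR (14 rose, 7 fell of 27) had camera adjusted p = 0.0572, with ASNS higher by 1.57. Drug transporter genes (7 rose, 7 fell of 21, adjusted p = 0.612) included ABCC4, higher by 3.21, and lysosome genes (9 rose, 10 fell of 24) had adjusted p = 0.977. ABCC4 was also higher in SKR6-Vector than in SKR6, by 2.28. Of 19 mesenchymal genes 8 rose and 2 fell in SKR6LR (camera adjusted p = 0.0604), with TAGLN higher by 5.44 and FN1 by 4.69 and the intermediate filament gene VIM at -0.30, not called. In SKR6CA 2 of 19 rose and 2 fell (camera adjusted p = 0.532).

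Camera called no list of markers of other cell types, but fry called the fibroblast (adjusted p = 8.46e-06), leukocyte (2.53e-05) and endothelial (0.00957) lists higher in SKR6LR. Fry also called the endothelial list higher in SKR6CA (0.0320) and in SKR6-Vector against SKR6 (0.0162). Of 10 fibroblast markers 0 passed the test in SKR6CA and 3 rose in SKR6LR, COL3A1 by 4.92, while COL1A1 and COL1A2 had -0.24 and -0.0014, not called. Of 10 leukocyte markers 1 rose in SKR6CA and 2 in SKR6LR, CSF1R by 2.32 and CD14 by 1.72, and PTPRC had 0.054, not called. Of 10 endothelial markers 2 rose in SKR6CA and 2 rose and 2 fell in SKR6LR, where CDH5 rose by 3.83 and PECAM1 had -0.021, not called. CDH5 was also higher in SKR6-Vector than in SKR6, by 2.96. Of 24 ribosomal protein genes 1 rose and 2 fell in SKR6CA and 6 fell in SKR6LR.

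Probe sets without a single gene name, 13522 in number once control probe sets were left out, also held calls at the level of probe sets. In SKR6CA against SKR6-Vector 1629 of them were called, in SKR6LR against SKR6 4359, and in SKR6-Vector against SKR6 1259.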
